A study of Homo sapiens with 8 samples.

How the data were processed

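RNA sequencing libraries of 2 diffuse large B cell lymphoma cell lines, HT and SUDHL6, were compared after 96 hours (day 4) with iEZH or DMSO, 2 libraries per group and 8 in all. Per the labels' protocols the cells grew in RPMI GlutaMAX medium with fetal bovine serum and penicillin/streptomycin, total RNA was taken, and reads were processed against hg19 with TopHat 1.4.1 and Cufflinks, whose version is not stated. The labels do not state the library kit, strandedness, annotation or normalization options.

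The authors deposited 1 table per line with FPKM (fragments per kilobase, scaled to the mapped reads) for each gene symbol and library. Per the file headers, only genes rated detectable were kept, a gene counting as detectable from 10 reads and as quantifiable from 50 reads. In the deposited FPKM values, 239 to 507 per library sit at 1 shared floor, 0.0613 FPKM in HT and 0.0712 in SUDHL6. The tables also hold a p-value per gene that the authors computed with a Tukey test, an FDR of it, and a fold, the ratio of the mean iEZH to the mean DMSO value in the deposited numbers; recomputing it matched 12391 of 12392 HT and 12105 of 12106 SUDHL6 values. The fold is missing for 1309 HT and 930 SUDHL6 genes, by a rule that the files do not state. Per the file headers, each library also has a count of total reads, 59563321 to 94821806, which the thresholds of HT take as mapped reads. Counts per gene were not analysed here, so counting intervals per gene are not given. The HT headers give a detection threshold of 10 reads as 0.0613 to 0.0691 FPKM. They give 1 such value per library whatever the length of the gene, so it does not equal 10 reads for every gene. The SUDHL6 header repeats 1 threshold for DMSO replicate 1 and iEZH replicate 2, although their read numbers differ.

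The sheets' columns were matched to the labelled samples through the sample information sheets, with 0 columns left unmatched. One HT gene (AASDH) with a value that is not a number was left out, and the symbol MARCH2 stands on 2 lines of the SUDHL6 table, both kept. Coordinates are those of the authors' tables on hg19, with starts counted from 1.

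Values were used as the authors normalized them. Genes with at least 1 FPKM in at least 2 of the 4 libraries of a line were tested, 11321 in HT and 11173 in SUDHL6. Log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with eBayes and trend, for iEZH against DMSO within each line, without a replicate block. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p of 0.05. The difference between lines (SUDHL6 minus HT) was the interaction term of 1 fit of the 8 libraries over 10426 genes tested in both. Shared calls were tested per direction with a one-sided Fisher exact test. Direction was checked as both iEZH libraries lying beyond both DMSO libraries, and as the change within each replicate number.

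The tests, filters, alternatives, the rule for named genes and 25 gene lists were written before the data were examined. The rule names, per line, the 10 largest rises and 10 largest falls among called genes whose iEZH libraries lie beyond both DMSO libraries, up to 4 called members of each list (or at most 2 members with the smallest p, as values), and EZH2, EZH1, EED, SUZ12, PRDM1, CDKN1A, TXNIP, BCL6 and MYC wherever measured. For the difference it names the 5 largest in each direction. Because short genes took most of the places, further genes are named from the longer ones, and the text says where this was done after their values were seen; further list members are given as values. Lists with at least 5 measured genes, 22 in HT and 21 in SUDHL6, were tested with camera at the preset correlation of 0.01, adjusted over the lists of a line, beside camera with an estimated correlation and fry. Standard errors, SDs and group means are given for 2 libraries each, and their number limits the precision.

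Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, median-ratio rescaling, quantile normalization, eBayes without trend, robust eBayes, both lines in 1 fit, a replicate block, an added threshold of 1 on the absolute log2 change, and leaving out each library in turn. Leaving out genes spanning under 300 bp, alone or with the block or the joint fit, was chosen after seeing the data. There were 367 HT and 330 SUDHL6 genes of that size, nearly all microRNAs and snoRNAs. The reason was that many of them moved between the floor and high FPKM. Of the 157 HT and 167 SUDHL6 ones that passed the filter, 93 and 101 were at the floor in at least 1 library. Camera on the difference between lines and camera without the filter were also added after seeing the data. For a check of bias, GC content and length came from the longest GENCODE transcript of each symbol, and no coordinates were taken from it.

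The limma fits were tested on simulated data with 200 genes changed in each line. Values were drawn around the real means, with lower means raised to 2 on the log2(FPKM + 1) scale. Jumps of short genes between the floor and high FPKM were not simulated, so the shares below do not describe such calls. On 11321 simulated HT genes, 145 were called, 5.52% of them unchanged ones, and 45% and 92% of genes changed by 1 and 2 on the log2 scale were recovered. On 11171 simulated SUDHL6 genes, 112 were called, 7.14% of them unchanged, with 18% and 86% recovered. The interaction on 10424 genes gave 238 calls, 8.4% of them unchanged, with 32.6% and 85.1% recovered. With short genes left out, 72% and 100% were recovered on 11164 HT genes and 53% and 98% on 11006 SUDHL6 genes, with 4.97% and 6.79% of calls on unchanged genes. With a simulated replicate effect, 44% and 87% were recovered on 11320 HT genes and 21% and 85% on 11172 SUDHL6 genes, with 1.5% and 0% of calls on unchanged genes. A simulated list of 30 shifted genes among 11321 gave a camera p of 2.75e-113 with the preset and 0.00148 with an estimated correlation. An unshifted list gave 0.892 and 0.926. These genes were drawn independently with equal spread, so the check does not cover camera on genes that vary together.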

Results

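Total RNA was sequenced from 2 diffuse large B cell lymphoma cell lines, HT and SUDHL6, after 96 hours with iEZH or with its solvent DMSO. The title of the series names iEZH as a small molecule inhibitor of PRC2, the complex whose EZH2 subunit methylates lysine 27 of histone H3. Each line had 2 DMSO and 2 iEZH libraries, so the 8 libraries form 4 groups of 2. In HT the libraries held 77232993 and 81858662 reads for DMSO and 79309616 and 72385330 for iEZH. In SUDHL6 they held 94821806 and 65345993 reads for DMSO and 59563321 and 71042701 for iEZH. Expression was deposited as FPKM for 13701 genes in HT and 13036 in SUDHL6. Some values of every library sit at 1 shared floor, 0.0613 FPKM in HT and 0.0712 in SUDHL6. Between libraries of a line, log2(FPKM + 1) correlated across genes spanning 300 bp or more at 0.97 to 0.99; genes are not independent replicates. Many genes spanning under 300 bp had values that jump between the floor and high FPKM. MicroRNA and small nucleolar RNA (snoRNA) genes and other genes of that size held 21% to 44.4% of the summed FPKM of a library. Results are therefore given with these short genes and, as an alternative chosen after seeing the data, without them. Same-numbered libraries deviated together in both lines, and a replicate block called 2482 HT and 2313 SUDHL6 genes instead of 69 and 30. The labels give the replicate numbers no meaning, so the main counts are those without the block.

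The transcripts of EZH2, EZH1, EED and SUZ12 did not pass the test in either line. EZH2 stood at 59.7 ± 5.47 FPKM (SD, n = 2) in HT with DMSO and at 52.8 ± 4.77 with iEZH, a log2 change of -0.18 (limma, adjusted p = 0.519), lower within both replicate numbers. In SUDHL6 EZH2 stood at 60.9 ± 3.15 and 51.2 ± 5.25 FPKM (log2 change -0.25, adjusted p = 0.401), again lower within both replicate numbers. EZH1 differed by -0.01 and 0.02 on the log2 scale, EED by -0.44 (adjusted p = 0.11) and -0.02, and SUZ12 by -0.27 and -0.26, in HT and SUDHL6. JARID2, an accessory subunit, had 5.14 and 9.01 FPKM in HT (log2 change 0.71, adjusted p = 0.0649) and 7.68 and 12.4 FPKM in SUDHL6 (0.63, adjusted p = 0.144). JARID2 passed in HT with short genes left out (adjusted p = 0.0378), as did a further accessory subunit, C17orf96 (7.1 and 15.45 FPKM, adjusted p = 0.0686 with short genes and 0.0319 without). An inhibitor acts on the enzyme, so these levels do not check the labels.

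In HT, iEZH raised SPOCK2, S100A1, RNF130, NPL, FILIP1L and CAMKV and lowered CHAC1, SESN2 and SLC43A1. SPOCK2, a secreted proteoglycan (hg19 chromosome 10, 73818792 to 73848790), rose from 3.92 ± 0.13 to 27.2 ± 2.11 FPKM (SD, n = 2; log2 change 2.52, SE 0.13, adjusted p = 0.00321). S100A1, a calcium-binding protein (chromosome 1, 153600873 to 153604513), rose from 1.97 ± 0.283 to 9.08 ± 0.0494 FPKM (1.77, SE 0.13, adjusted p = 0.0194). RNF130 rose from 1.27 to 5.75 FPKM (1.57, adjusted p = 0.0235), NPL from 2.72 to 9.86, and FILIP1L from 0.0653 to 2.1. CHAC1, which degrades glutathione (chromosome 15, 41245636 to 41248717), fell from 71.7 ± 13.7 to 12.5 ± 3.35 FPKM (log2 change -2.44, SE 0.23, adjusted p = 0.0389). SESN2, a stress sensor (chromosome 1, 28585963 to 28609002), fell from 41.8 ± 5.03 to 13.7 ± 1.17 FPKM (-1.54, SE 0.14, adjusted p = 0.0389), and SLC43A1, an amino acid transporter, from 85.1 to 30.8 (-1.44, adjusted p = 0.0425). The other 3 protein-coding falls, named after their values were seen, were WARS (-1.18), SHMT2 (-1.11) and SLC1A5 (-1.02), a tRNA synthetase, a serine hydroxymethyltransferase and a glutamine transporter. In each of these genes both iEZH libraries lay beyond both DMSO libraries, and the change had the same sign within both replicate numbers. PPAN-P2RY11 had 0.218 and 9.26 FPKM (3.07, adjusted p = 0.0126), but this readthrough transcript overlaps PPAN and P2RY11, so its reads are uncertain. FILIP1L, CAMKV and PPAN-P2RY11 lay under 1 FPKM in both DMSO libraries and passed the filter only through iEZH. Their sign is therefore not free of the filter.

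Of 11321 HT genes tested with limma, 69 passed at an adjusted p of 0.05, 52 up and 17 down, and 2424 had an unadjusted p under 0.05. Of the 69, 18 spanned under 300 bp, 7 up and 11 down, and among them were the largest changes. MIR1204, SNORD36C, SNORD65 and SNORD59A led the rises, and SNORD29, MIR4664, SNORD96A and SNORD45C the falls. MIR1204 was at the floor in both DMSO libraries and averaged 2594 FPKM with iEZH (adjusted p = 1.96e-05), and SNORD29 averaged 4766 FPKM with DMSO and was at the floor in both iEZH libraries (adjusted p = 1.44e-05); no fold is given against the floor. With short genes left out, 615 of 11164 genes passed, 454 up and 161 down, and all 51 longer genes of the first count were among them; CHAC1, DDIT3, CTH, SPNS3, PSAT1 and ATF5 then led the falls. Both iEZH libraries lay beyond both DMSO libraries in 51.9% of genes, where chance gives 33.3%. The authors' own FDR, from a Tukey test on FPKM, was under 0.05 for 209 HT genes, of which 84 were higher and 17 lower with iEZH and 108 had every library at the floor. The count of 69 became 108 without DMSO replicate 2 (50 up and 58 down), 45 without iEZH replicate 1 (18 and 27) and 35 without iEZH replicate 2 (12 and 23), so the excess of rises did not hold without these libraries. Without the filter it became 12, and each HT gene of 300 bp or more named above as called lost its call, SPOCK2 at an adjusted p of 0.0504 and CHAC1 at 0.0891; with both lines in 1 fit it became 648. S100A1, RNF130 and FILIP1L lost their calls without iEZH replicate 2 (adjusted p = 0.0525, 0.0587 and 0.0594), and NPL, CAMKV, SESN2 and SLC43A1 without either iEZH library (up to 0.0617, 0.0723, 0.071 and 0.0723). WARS, SHMT2 and SLC1A5 lost theirs whichever 1 of the 4 libraries was left out (up to 0.112, 0.142 and 0.154), whereas SPOCK2 (up to 0.00964) and CHAC1 (up to 0.0465) kept theirs without each library.

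**Figure D1:**
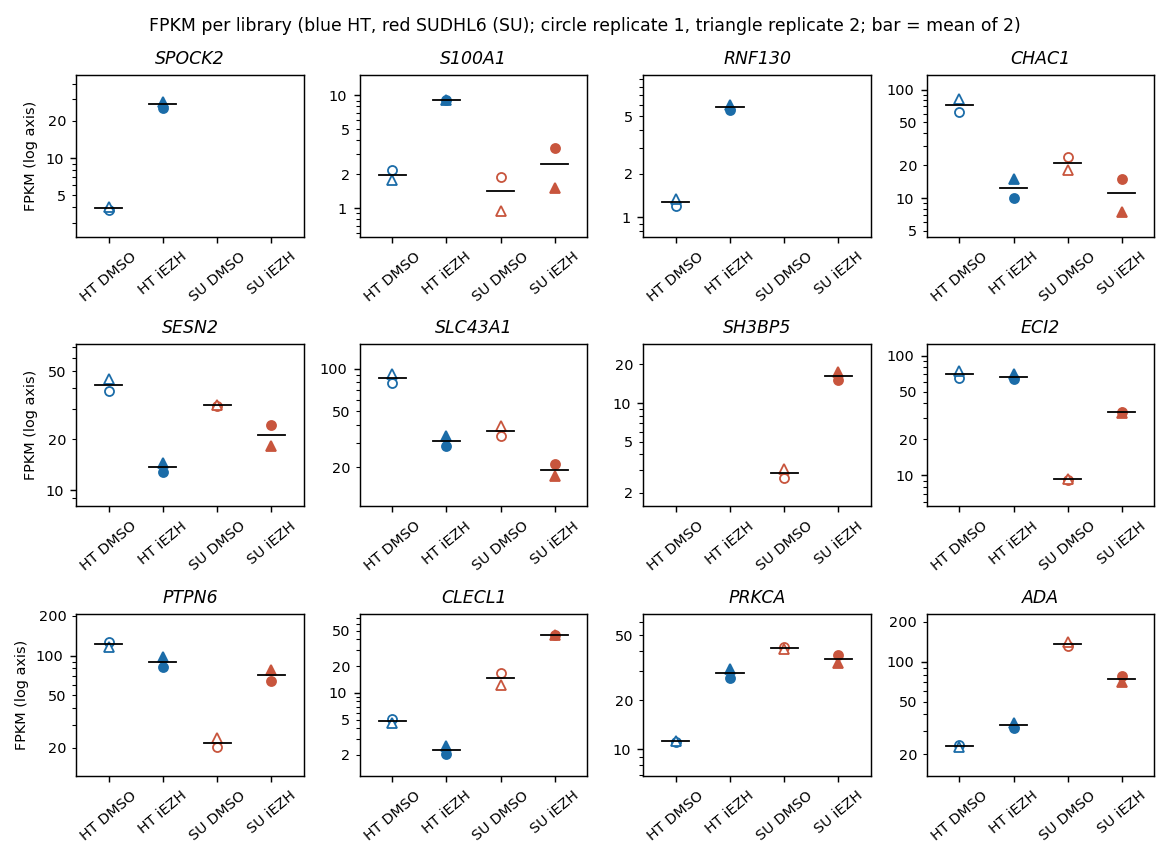
FPKM per library on log axes for 12 genes in HT (blue) and SUDHL6 (red, SU), with open symbols for DMSO, filled symbols for iEZH, circles for replicate 1, triangles for replicate 2 and bars for the mean of 2; a gene is drawn only in a line where it was tested. CHAC1 averaged 71.7 FPKM in HT with DMSO and 12.5 with iEZH, and SPOCK2 3.92 and 27.2.

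Among the gene lists fixed before the data were examined, the amino acid and unfolded protein stress genes had the largest median fall in HT. Of the 22 measured, 18 were lower, with a median log2 change of -0.80. Beside CHAC1 and SESN2 stood DDIT3 (99.2 and 22.5 FPKM, adjusted p = 0.068), PSAT1 (183 and 57.1, adjusted p = 0.0556), ASNS (365.5 and 134.2, adjusted p = 0.114) and PHGDH (223 and 92.2, adjusted p = 0.072), all lower with iEZH. Over all genes 2 of the list fell and the rest did not pass, and with short genes left out 11 fell, among them DDIT3 (adjusted p = 0.0266) and PSAT1 (0.0231). Adjusted over the list alone 15 fell and 1, HSPA5, rose. The list ranked below the other genes by camera with a preset correlation (adjusted p = 4.39e-07; adjusted p = 0.51 with an estimated correlation).

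DNA replication and mitosis genes were lower in HT as groups. Of 34 DNA replication and S phase genes, 33 were lower, with a median log2 change of -0.58 that both rescalings kept negative. PRIM1 had 34.4 and 16.1 FPKM (log2 change -1.05, adjusted p = 0.0524), TK1 120.5 and 60.8 (-0.98, adjusted p = 0.0547) and CDT1 64.1 and 33.3 (-0.92, adjusted p = 0.059). No member passed over all genes, but with short genes left out 10 fell, among them PRIM1 (adjusted p = 0.022), TK1 (0.025) and CDT1 (0.0271), and 24 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.44e-14; adjusted p = 0.51 with an estimated correlation). All 34 measured G2/M genes were lower, with a median of -0.37, among them NDC80 (89.4 and 52.5 FPKM), CCNA2 (109 and 66.3) and AURKB (135.5 and 79.7). None passed over all genes, 5 fell with short genes left out (these 3 at adjusted p = 0.0284, 0.0314 and 0.031, with CCNB2 and KIF2C), and 8 fell adjusted over the list alone (camera adjusted p = 1.14e-11; adjusted p = 0.51 with an estimated correlation).

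The few developmental and neuronal genes measured in HT were mostly higher. Of 65 developmental transcription factors, textbook Polycomb targets, 7 passed the filter. Their median was 0.49, and it was 0.80 with a pseudocount of 0.1 and 0.32 with quantile normalization. HOXD8, HOXA5 and FOXA1 lay under 1 FPKM in both DMSO libraries and passed the filter only through iEZH. The sign of these 3 is therefore not free of the filter. Without the filter, a test added after seeing the data, 13 of 14 were higher with a median of 0.22 (camera adjusted p = 0.000454; adjusted p = 0.483 with an estimated correlation). SOX9 had 12.9 and 22.6 FPKM (adjusted p = 0.0646) and HOXD8 0.944 and 1.87 (adjusted p = 0.0879). None passed over all genes, 1, SOX9, rose with short genes left out (adjusted p = 0.0348), and 5 rose adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.51 with an estimated correlation). Of 22 neuronal genes 5 passed the filter, with a median of 0.90, including TUBB3 (222.9 and 415.4 FPKM, adjusted p = 0.056, and 0.0251 with short genes left out) and CHGB (0.314 and 1.65, adjusted p = 0.106), which passed the filter only through iEZH. Without the filter 8 of 8 neuronal genes were higher with a median of 0.44 (camera adjusted p = 0.00136, and 0.483 with an estimated correlation). The deposited genes had themselves been kept as detectable, so the unfiltered results of both lists may still depend on a filter. Markers of other cell types were also mostly higher in HT without the filter. These were 8 of 9 T and NK, 7 of 9 myeloid and 4 of 4 epithelial and stromal markers, so the rise is not shown to be particular to the developmental and neuronal lists. No neuronal gene passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.0043, and 0.51 with an estimated correlation). Of 29 MYC and ribosome biogenesis genes, 27 were higher with a median of 0.33 (camera adjusted p = 0.00737; adjusted p = 0.903 with an estimated correlation). MYC itself had 72.2 ± 14.9 and 152.7 ± 4.72 FPKM (log2 change 1.08, adjusted p = 0.0577) and was the 1 member that rose adjusted over the list alone, with 0 over all genes and adjusted p = 0.0252 with short genes left out. BCL2 family and death receptor genes had a median of -0.16, with 18 of 24 lower, 0 called over all genes, PMAIP1 and BBC3 falling with short genes left out, and BBC3 falling adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.727 with an estimated correlation). NF-kB target genes had a median of -0.09, with 13 of 17 lower, 0 called over all genes, 2 up and 2 down with short genes left out, and 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.0298; adjusted p = 0.0619 without the filter and 0.737 with an estimated correlation). The medians of the 8 lists past the threshold kept their sign under median-ratio rescaling and quantile normalization. No list passed with an estimated correlation, and by fry, which asks whether a list moves 1 way, the smallest adjusted p was 0.0514.

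The other HT lists did not pass camera. Their medians and camera adjusted p were -0.18 and 0.29 for PRC2 subunits, 0.06 and 0.376 for PRC1 subunits and H3K27 demethylases, 0.10 and 0.542 for cyclin-dependent kinase inhibitors, 0.06 and 0.895 for germinal centre B cell genes, and 0.15 and 0.436 for plasma cell genes. They were 0.10 and 0.769 for memory and naive B cell genes, -0.03 and 0.823 for B cell receptor signalling, -0.11 and 0.242 for MHC class II, 0.15 and 0.895 for MHC class I, and 0.02 and 0.436 for interferon response genes. They were 0.00 and 0.779 for p53 targets, -0.09 and 0.0638 for cholesterol biosynthesis, 0.01 and 0.542 for glucose metabolism, and 0.00 and 0.316 for housekeeping genes. SESN2, in the p53 list, was the 1 member of these lists called over all genes. Without short genes 7 interferon response genes, 2 PRC2 subunits and PHC2, a PRC1 subunit, rose. ITM2C rose and XBP1 and DERL3 fell among plasma cell genes, and SESN1 rose and SESN2 fell among p53 targets. Among memory and naive B cell genes IL4R rose and 1 other member fell. SERPINA9, a germinal centre gene, rose, and CDKN2D, SLC2A3 and LCK fell. Adjusted over the list alone, 8 interferon response genes rose, led by OASL (0.718 and 2.15 FPKM) and IFITM1 (8.12 and 16.5). PRC1 genes gave 4 up, PRC2 subunits 2 up and 2 down, plasma cell genes 2 up and 2 down, memory and naive B cell genes 1 up and 2 down, p53 targets 1 up and 1 down, and kinase inhibitors 1 down; the remaining lists large enough to test gave 0. The median and the mean or the camera direction had opposite signs for kinase inhibitors, memory and naive B cell genes, B cell receptor signalling, MHC class I, glucose metabolism and housekeeping genes. Median-ratio rescaling or quantile normalization changed the sign of the median for kinase inhibitors, B cell receptor signalling, interferon response, glucose metabolism and housekeeping genes. BCL6 (402.2 and 444.3 FPKM) had an adjusted p of 0.692 and TXNIP (5.56 and 17.4) of 0.141, with TXNIP higher within both replicate numbers. Markers of other cell types that passed the filter were too few to test in HT: LCK (132.2 and 77.8 FPKM) and CD4 of 22 T and NK cell markers, CD33 and CD68 of 22 myeloid, and LUM and DCN of 21 epithelial and stromal markers, with medians of -0.20, -0.21 and 0.28. Adjusted over the list alone LCK fell and CD4 rose. These medians rest on 2 genes each. Without the filter the T and NK median was 0.22 over 9 genes, 8 higher (camera adjusted p = 0.11), the myeloid median 0.24 over 9, 7 higher (0.436), and the epithelial and stromal median 0.18 over 4, too few to test.

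**Figure D2:**
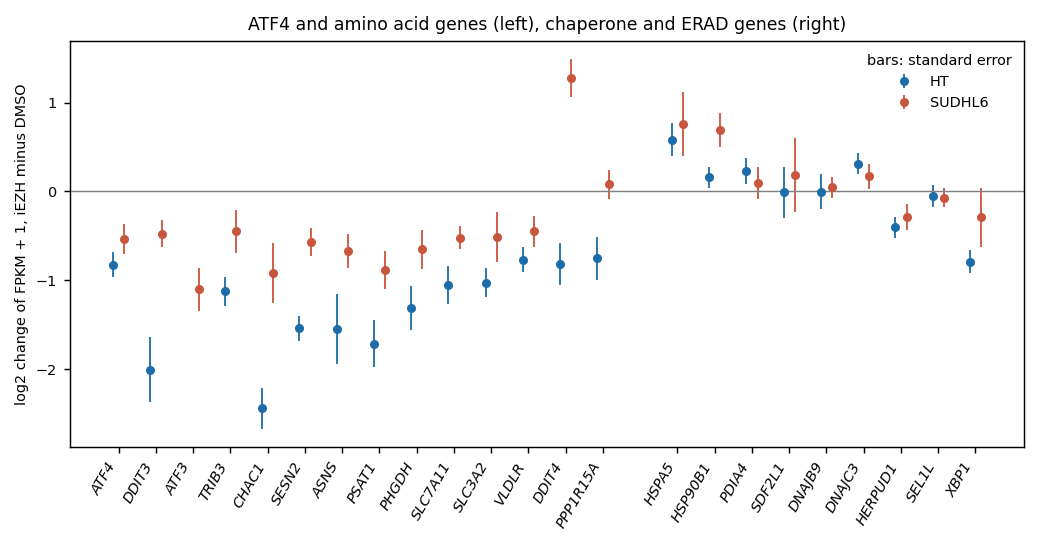
Log2 change of FPKM + 1, iEZH minus DMSO, with limma's standard error, for each measured gene of the stress list in HT (blue) and SUDHL6 (red). In HT the ATF4 and amino acid genes on the left have a median of -1.12 and the chaperone and ERAD genes on the right a median of 0.

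In SUDHL6, iEZH raised SH3BP5, ECI2 and CCL4. SH3BP5, a binding partner of the kinase BTK (hg19 chromosome 3, 15296357 to 15382901), rose from 2.84 ± 0.347 to 16.3 ± 1.68 FPKM (SD, n = 2; log2 change 2.17, SE 0.13, adjusted p = 0.0159). ECI2, an enoyl-CoA isomerase (chromosome 6, 4115927 to 4135831), rose from 9.3 ± 0.129 to 33.7 ± 0.19 FPKM (1.75, SE 0.10, adjusted p = 0.0114). CCL4, a chemokine and the 1 list member called over all genes, rose from 0.833 ± 0.11 to 3.69 ± 0.0326 FPKM (1.36, SE 0.11, adjusted p = 0.0458). CCL4 passed the filter only through iEZH, so its sign is not free of the filter. The other 4 longer genes that passed, named after their values were seen, were ACSL1 (1.39), BHLHE40 (1.38), SERPINB6 (1.37) and BASP1P1 (1.69), a pseudogene whose reads are uncertain. Both iEZH libraries lay above both DMSO libraries for these 7 genes, and no gene spanning 300 bp or more passed as lower.

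Of 11173 SUDHL6 genes tested with limma, 30 passed, 17 up and 13 down, and 2095 had an unadjusted p under 0.05. Of the 30, 23 spanned under 300 bp, 10 up and 13 down. SNORD36C, MIR2110, MIR4784 and SNORD38B led the rises, from the floor in both DMSO libraries to 3257 FPKM for SNORD36C and 3196 for MIR2110. SNORD58B, SNORD51 and MIR1914 led the falls, and SNORD116-16, SNORD116-17, SNORD116-18, SNORD116-19 and SNORD116-21 carried identical values, so they count as 1 signal. With short genes left out, 2 of 11006 genes passed, SH3BP5 and ECI2 (adjusted p = 0.0464 for each), and 2164 had an unadjusted p under 0.05; CCL4 then had 0.0643. Both iEZH libraries lay beyond both DMSO libraries in 49.5% of genes, where chance gives 33.3%. The authors' FDR was under 0.05 for 51 SUDHL6 genes, 33 higher and 18 lower. The count of 30 became 49 without DMSO replicate 1 and 348 with both lines in 1 fit. Without the filter ECI2 kept its call, and SH3BP5 (adjusted p = 0.0799), CCL4 (0.0852), ACSL1, BHLHE40, SERPINB6 and BASP1P1 lost theirs. SH3BP5 kept its call without each library (up to 0.0326), ECI2 lost it without DMSO replicate 2 (0.0504), BASP1P1 without either DMSO library (up to 0.068), and CCL4, ACSL1, BHLHE40 and SERPINB6 whichever 1 of the 4 was left out (up to 0.16, 0.122, 0.104 and 0.117).

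DNA replication genes were also lower as a group in SUDHL6. All 34 measured S phase genes were lower with a median log2 change of -0.54, led by CDT1 (92.2 and 43.3 FPKM, adjusted p = 0.107), E2F1 (70.2 and 33.2, adjusted p = 0.119) and MCM6 (92.8 and 57.2, adjusted p = 0.128). None passed over all genes and 8 fell adjusted over the list alone (camera adjusted p = 3.11e-16, and 0.952 with an estimated correlation). With the replicate block 29 of them fell over all genes. Of 34 G2/M genes 31 were lower with a median of -0.23, including CCNA2 (41.4 and 29 FPKM), with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 3.29e-07; adjusted p = 0.572 with an estimated correlation). The stress list had a median of -0.45 over 23 genes, 15 lower and 8 higher, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0075; adjusted p = 0.952 with an estimated correlation). In it DDIT4 had 71.9 and 172.6 FPKM, higher with iEZH (adjusted p = 0.119), while ATF3 had 3.55 and 1.18 and ASNS 261.8 and 165.9. Germinal centre B cell genes had a median of -0.20, with 19 of 25 lower, 0 called over all genes, and 3 up and 3 down adjusted over the list alone (camera adjusted p = 0.0459; adjusted p = 0.952 with an estimated correlation). BCL6 (124.9 and 76.6 FPKM, log2 change -0.69, adjusted p = 0.133) and S1PR2 were lower, and LMO2 and SERPINA9 higher, among the members that passed adjusted over the list alone. These 4 medians kept their sign under median-ratio rescaling and quantile normalization, and by fry the smallest adjusted p was 0.188.

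The other SUDHL6 lists did not pass camera. Their medians and camera adjusted p were -0.20 and 0.242 for PRC2 subunits, 0.12 and 0.791 for PRC1 subunits and H3K27 demethylases, 0.10 and 0.668 for developmental transcription factors, -0.12 and 0.545 for cyclin-dependent kinase inhibitors, 0.08 and 0.668 for plasma cell genes, and 0.37 and 0.541 for memory and naive B cell genes. They were 0.06 and 0.791 for B cell receptor signalling, 0.27 and 0.582 for MHC class II, 0.20 and 0.584 for MHC class I, 0.18 and 0.618 for interferon response genes, 0.05 and 0.952 for the BCL2 family, and 0.16 and 0.813 for p53 targets. They were 0.00 and 0.791 for NF-kB targets, 0.21 and 0.586 for MYC and ribosome biogenesis, 0.17 and 0.106 for cholesterol biosynthesis, 0.04 and 0.824 for glucose metabolism, and 0.01 and 0.586 for housekeeping genes. Over all genes CCL4, in the NF-kB list, was the 1 called member, and with short genes left out no list member passed. Adjusted over the list alone, memory and naive B cell genes gave 4 up and 1 down, with CCR7 (3.12 and 15.3 FPKM, adjusted p = 0.118) and FCER2 (1.67 and 8.46, adjusted p = 0.137) higher. P53 targets and NF-kB targets gave 3 up and 2 down each, B cell receptor signalling 1 up, PTPN6, the BCL2 family 1 down, HRK, and the remaining lists large enough to test 0. The median and the mean or the camera direction had opposite signs for plasma cell, BCL2 family, NF-kB target, glucose metabolism and housekeeping genes. Quantile normalization changed the sign of the median for developmental transcription factors, B cell receptor signalling, the BCL2 family, glucose metabolism, housekeeping and neuronal genes. MYC (168.1 and 171.4 FPKM) had an adjusted p of 0.946, CDKN1A (18.5 and 34.9) of 0.438 and TXNIP (23.6 and 44.9) of 0.195. Neuronal genes (3 measured, median 0.09) and the markers of other cell types that passed the filter were too few to test: LCK of the T and NK cell markers (median -0.61), CD68 and MS4A7 of the myeloid (median 0.31), and ACTA2 of the epithelial and stromal markers (0.238 and 1.87 FPKM, median 1.22). Adjusted over these lists alone LCK fell and ACTA2 rose. The change of ACTA2 was 1.72 with a pseudocount of 0.5 and 2.73 with 0.1, so its size depends on the pseudocount. ACTA2 also passed the filter only through iEZH. Without the filter the neuronal median was 0.51 over 5 genes, 4 higher (camera adjusted p = 0.531), and the T and NK, myeloid and epithelial and stromal medians were -0.33 over 2, 0.12 over 4 and 0.12 over 3, too few to test. PRDM1 was not tested in either line, and CDKN1A was tested only in SUDHL6.

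**Figure D3:**
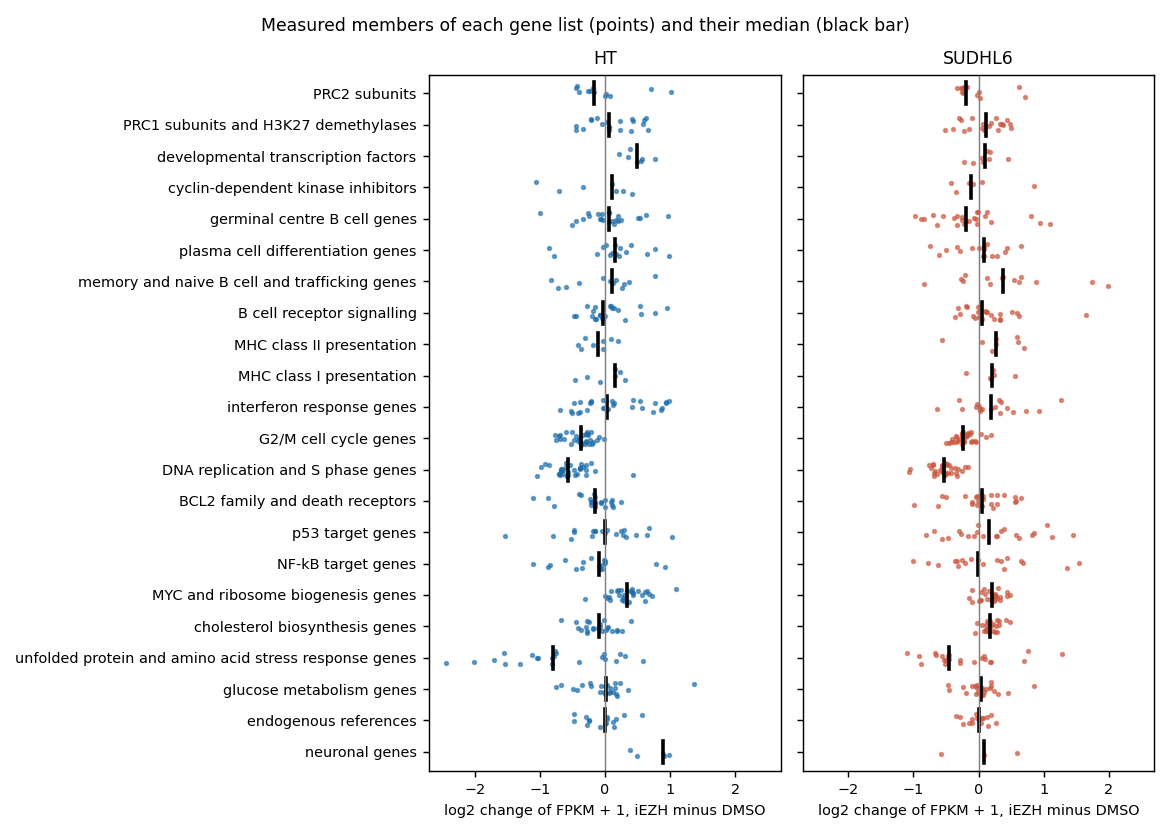
Log2 change of FPKM + 1, iEZH minus DMSO, of each measured member (points) of the gene lists in HT (left) and SUDHL6 (right), with the median of each list as a black bar. The S phase medians lie at -0.58 in HT and -0.54 in SUDHL6 and the stress medians at -0.80 and -0.45, and all 4 stayed negative under both rescalings.

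The lines were then compared for shared and for differing responses to iEZH. SNORD36C was the only gene called upward in both lines, out of 38 and 12 calls among 10426 genes tested in both, where independent lists share 0.0437 (one-sided Fisher exact p = 0.0429), and it is a short gene. No gene was called downward in both, and MIR4315-1 was called up in HT and down in SUDHL6. With short genes left out no gene was shared, from 325 upward and 154 downward HT calls and 1 upward SUDHL6 call. Independent lists would then share 0.0315 upward and 0 downward, so this count cannot tell whether the lines share responses. Across the 10308 longer genes the log2 changes of the lines correlated at r = 0.44 and rho = 0.436, and with short genes at r = 0.118 and rho = 0.422; genes are not independent replicates. The overlap depends on the fit. With a replicate block and short genes left out 1442 genes were shared, 881 up and 561 down. Independent lists share 371 and 186, but the labels give the replicate numbers no meaning. With both lines in 1 fit 129 genes were shared, 97 up and 32 down, where independent lists share 10.6 and 1.9, and 164 with short genes left out; this fit gives both lines the same variance per gene, so its calls are not independent. The overlap of 1 gene became 7 with robust eBayes, 3 without HT DMSO replicate 2 and 2 without either SUDHL6 iEZH library.

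PTPN6, CLECL1, ECI2, PRKCA, ADA and NETO2 responded differently in the lines. PTPN6, a tyrosine phosphatase of B cell receptor signalling (hg19 chromosome 12, 7055740 to 7070479), went from 121.6 ± 6.59 to 89.1 ± 11 FPKM in HT and from 21.9 ± 2.35 to 70.9 ± 9.19 in SUDHL6 (SD, n = 2; SUDHL6 minus HT 2.10 on the log2 scale, SE 0.21, adjusted p = 0.0274). CLECL1, a lectin-like surface protein (chromosome 12, 9868456 to 9885895), went from 4.87 ± 0.371 to 2.29 ± 0.35 FPKM in HT and from 14.5 ± 3.01 to 44.3 ± 0.108 in SUDHL6 (2.40, SE 0.22, adjusted p = 0.0194). ECI2 stood at 70.4 and 67 FPKM in HT against its rise in SUDHL6 (1.82, adjusted p = 0.0149). PRKCA, a protein kinase C (chromosome 17, 64298926 to 64806862), went from 11.2 ± 0.176 to 29.3 ± 2.6 FPKM in HT and from 41.7 ± 0.842 to 35.9 ± 2.92 in SUDHL6 (-1.53, SE 0.16, adjusted p = 0.0274). ADA had 23.1 and 33 FPKM in HT and 135.9 and 74.3 in SUDHL6 (-1.36, adjusted p = 0.0451), and NETO2 5.3 and 11 FPKM in HT and 22 and 16.8 in SUDHL6 (-1.30, adjusted p = 0.0415). In each line both iEZH libraries lay on the same side of both DMSO libraries for these genes, except for ECI2 in HT.

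Of 10426 genes tested in both lines, limma's interaction term called 11, with 6 changes more positive in SUDHL6 and 5 more positive in HT, and 1153 had an unadjusted p under 0.05. The other 5 were the short genes SNORD29, MIR3916, SNORD83B, SNORA26 and MIR4315-1. With short genes left out 7 of 10308 passed, the same 6 longer genes and ID2 (adjusted p = 0.0484), which had 52 and 40.8 FPKM in HT and 8.15 and 22.7 in SUDHL6, and 1132 had an unadjusted p under 0.05. The count of 11 became 5 without HT DMSO replicate 1, 4 without HT DMSO replicate 2, 6 and 5 without HT iEZH replicates 1 and 2, and 5 and 7 without SUDHL6 iEZH replicates 1 and 2. PTPN6, PRKCA, ADA and NETO2 lost their calls whichever 1 of the 8 libraries was left out (adjusted p up to 0.206, 0.231, 0.239 and 0.231), and CLECL1 and ECI2 lost theirs except where a SUDHL6 DMSO library was the one left out (up to 0.136 and 0.0985). All 11 kept the sign of the difference throughout, which was likely in advance for genes selected on these same libraries.

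**Figure D4:**
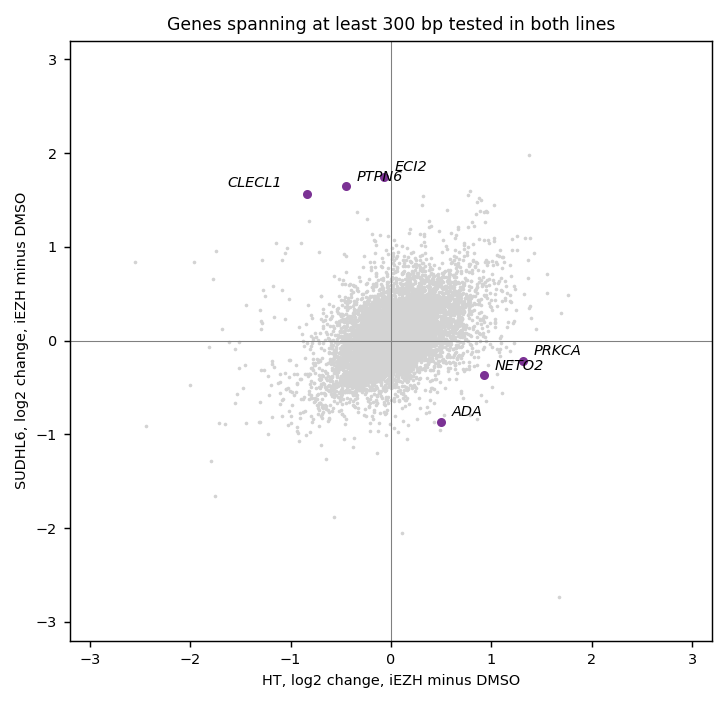
Log2 change with iEZH in HT (horizontal) and in SUDHL6 (vertical) for 10308 genes spanning at least 300 bp and tested in both lines, with the genes called by the interaction term in purple. CLECL1, PTPN6 and ECI2 lie above the main cloud and PRKCA, NETO2 and ADA below it.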

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

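The tests of the gene lists on the difference between lines, of single fragments behind short genes, of the spread between replicates and of genes just beyond the threshold were chosen only after the results were seen; the interaction test of single genes was planned.

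The difference of the iEZH effect, SUDHL6 minus HT, passed limma's interaction test for 11 genes (adjusted p from 0.000289 to 0.0451). Among the longer ones CLECL1 differed by 2.40 on the log2 scale, PTPN6 by 2.10, ECI2 by 1.82, PRKCA by -1.53, ADA by -1.36 and NETO2 by -1.30. CLECL1 and PTPN6 were higher with iEZH in both SUDHL6 iEZH libraries and lower in both HT ones, and PRKCA, ADA and NETO2 showed the reverse. The short genes differed by 12.35 (SNORD29), 10.04 (MIR3916), 9.57 (SNORD83B), -9.61 (SNORA26) and -18.25 (MIR4315-1); each has a group wholly at the floor, so these sizes depend on the pseudocount and are no bounds.

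Gene lists were also compared between the lines by camera on the interaction, which was not part of the planned tests. No list passed with an estimated correlation, and 5 did with the preset one. Stress response genes had a median of -0.80 in HT and -0.37 in SUDHL6 over the 22 genes tested in both (adjusted p = 0.000253; adjusted p = 0.658 with an estimated correlation). Cholesterol biosynthesis genes had -0.09 and 0.17 (adjusted p = 0.00244; 0.751 with an estimated correlation), BCL2 family genes -0.16 and 0.06 (adjusted p = 0.00485; 0.658), G2/M genes -0.37 and -0.23 (adjusted p = 0.0114; 0.658) and germinal centre genes 0.06 and -0.21 (adjusted p = 0.0165; 0.814).

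Short genes such as SNORD29 and MIR4664 made up 18 of 69 calls in HT and 23 of 30 in SUDHL6. A candidate explanation is that their FPKM rests on single fragments, scaled by a small length. The length that Cufflinks used is not stated, and the deposited span alone would give a single fragment a far smaller value. Ratios between short genes of equal span within a library were whole numbers, to within 1%, in 68.4% of cases, against 4.11% for spans differing by 1 to 5 bp. If such genes switch on and off by chance, a split by treatment should be found in 33.3% of those at the floor in exactly 2 of 4 libraries, and it was found in 38.6% in HT (22 of 57, 95% exact interval 26% to 52.4%) and in 40.3% in SUDHL6 (25 of 62, 28.1% to 53.6%). The other splits were by replicate number, 24 in HT and 21 in SUDHL6, and crossed, 11 and 16, so crossed splits were fewer than splits by treatment. Libraries of the same replicate number may deviate together, so 33.3% need not be the share without an effect. Chance switching may still account for such calls, and an effect of iEZH on some of them stays open.

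With short genes left out, 615 genes passed in HT and 2 in SUDHL6, although 2550 and 2164 had an unadjusted p under 0.05. The gap depends on the fit, since 754 and 457 passed with both lines in 1 fit. With a replicate block 3743 and 3780 passed, so the gap is absent there. A wider typical spread in SUDHL6 is argued against, since its median standard error was 0.939 times that of HT. The median does not show how far the spread varies between genes. Limma's prior degrees of freedom, lower where it varies more, were 3.39 in SUDHL6 and 4.78 in HT. Lower ones give larger p-values, and their part in the gap was not tested. Smaller changes in SUDHL6 cannot be told apart from equal ones, because the SD of its log2 changes was 0.896 times that of HT, between the bounds set beforehand. Many SUDHL6 genes may lie just beyond the threshold: at an adjusted p of 0.1 there were 510 in SUDHL6 and 1309 in HT. A biological difference between the lines stays open and was not tested by these counts.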

How the results depend on the processing

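The settings that leave out short genes, alone or combined, the list tests without a filter and the tests on depth were chosen after the results were seen; the others were fixed beforehand. Where a count moved, the cause was not tested, except that fewer genes or libraries enter under some settings.

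For HT, 69 genes became 12 without a filter, 41 with the stricter filter, 32 with quantile normalization, 497 with robust eBayes, 648 with both lines in 1 fit, 615 without short genes and 754 without short genes in 1 fit. For SUDHL6, 30 genes became 348 with both lines in 1 fit, 2 without short genes and 457 without short genes in 1 fit. For the difference between lines, 11 became 17 with a pseudocount of 0.1, 18 without a filter and 7 without short genes. The overlap of 1 became 7 with robust eBayes, 129 in 1 fit, 0 without short genes and 164 without short genes in 1 fit. Apart from the block and left-out libraries given below, counts under the other settings stayed within 1.5 times the first value. The share of HT calls that were up was 75.4%, and 33.3%, 63.4% and 59.4% without a filter, with the stricter filter and with quantile normalization. It was 58.3% and 46.3% without DMSO replicates 1 and 2 and 40% and 34.3% without iEZH replicates 1 and 2.

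Leaving out each library in turn gave 35 to 108 genes in HT (108 without DMSO replicate 2, 45 and 35 without iEZH replicates 1 and 2), 30 to 49 in SUDHL6 (49 without DMSO replicate 1), 4 to 15 for the difference and an overlap of 1 to 3. The lone library of a group is then assumed to vary like the others.

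By camera 8 lists passed in HT and 4 in SUDHL6, the same lists with a pseudocount of 0.1 and without short genes. Without a filter 8 and 4 passed, cholesterol biosynthesis replacing NF-kB targets in HT; 0 passed in either line with an estimated correlation or with fry. The 69 and 30 genes kept their sign in every setting in which they were tested, as did the 11 differences, and no called list reversed. These were selected on the same libraries for clear changes, so a kept sign was likely in advance and is little support. Some medians of lists that did not pass changed sign with rescaling. Of 94 named HT results 22 lost their call without a filter, 7 with quantile normalization, 3 of the 82 tested with the stricter filter, 1 with a pseudocount of 0.1 and 6 of 74 in 1 fit; without DMSO replicates 1 and 2 and iEZH replicates 1 and 2 these were 5, 3, 10 and 14. Of 80 in SUDHL6 8 lost it without a filter, 8 of 58 in 1 fit, 5 of 61 without short genes, 1 of 70 with the stricter filter, and 1 each with either pseudocount, quantile normalization or robust eBayes; without DMSO replicates 1 and 2 and iEZH replicates 1 and 2 these were 5, 6, 4 and 4.

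The labels give no meaning to the replicate numbers, and 2 pairs per line are too few to settle it. The main fit therefore leaves them out. Same-numbered libraries did deviate together, with correlations given below, so the unblocked counts may understate the genes that respond. With a replicate block 2482 genes passed in HT, 2313 in SUDHL6, 543 for the difference and 803 in the overlap; without short genes and with the block these were 3743, 3780, 1270 and 1442, so the gap of 615 against 2 is absent with the block. With the block 8 lists passed in HT and 6 in SUDHL6, 0 with an estimated correlation (smallest adjusted p 0.673 and 0.835), and by fry 0 in HT (0.118) and B cell receptor signalling in SUDHL6 (0.0248). On simulated data with a replicate effect the block recovered 89% and 43% of genes changed by 1 in HT and SUDHL6. Of its calls 6.97% and 5.56% were on unchanged genes. With short genes left out it recovered 94% and 89%, with 5.37% and 6% of calls on unchanged genes. Without a simulated replicate effect and with short genes kept the block recovered 1% and 0% of genes changed by 1. Of its calls 8.05% and 7.04% were on unchanged genes. With short genes left out the block then recovered 87% and 55%, against 72% and 53% without the block. Of the blocked calls 11.4% and 7.27% were on unchanged genes. All 69 and 30 genes were among the blocked calls.

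The difference between replicates 1 and 2 correlated between DMSO and iEZH across genes at 0.27 in HT and 0.19 in SUDHL6 (0.62 and 0.73 without short genes). Across lines it correlated at 0.44 to 0.71 without short genes. Each of these values lies above 0.1, the correlation taken to count as pairing. A difference in depth is argued against, because groups whose depth ratios point opposite ways still correlated at 0.52 or more. GC content and transcript length are argued against as the whole cause, because the mean correlation was 0.60 before and 0.57 after removing both (89.4% of genes had a value). A shared day or library batch may stay behind it, but the labels name none. Depth per gene is unknown, so limits near the 10-read threshold could not be set.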

Other observations

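The tests of silent genes and of the parts of the stress list below were chosen only after the results were seen.

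Genes silent with DMSO appeared with iEZH more often than the reverse. Among genes spanning 300 bp or more, 41 in HT had both DMSO libraries under 0.5 FPKM and both iEZH libraries at 1 FPKM or more, and 2 had the opposite order, a ratio of 20.5. In SUDHL6 there were 20 and 2, a ratio of 10. Splitting the same libraries by replicate number gave 0 and 1 genes in HT and 2 and 2 in SUDHL6. In HT DLX2 was at the floor in both DMSO libraries and averaged 2.01 FPKM with iEZH, and SPP1 had 0.335 and 2.13, S100A6 0.13 and 1.48 and DLX1 0.221 and 1.15 FPKM. In SUDHL6 IL18 had 0.322 and 2.26, SPARC 0.347 and 2.56 and MT2A 0.342 and 1.95 FPKM. DLX2 passed limma's test (adjusted p = 0.0389, but 0.067 without iEZH replicate 2 and 0.0891 without the filter, which it passed only through iEZH), and the others named here did not. No gene was among the 41 and the 20 at once. Of them 26 and 15 were among the 12051 genes present in both tables, where chance gives 0.0324 shared genes, so this neither shows nor excludes shared targets. Loss of PRC2 activity may switch on silent genes; chromatin marks were not analysed here.

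The stress list falls into ATF4 and amino acid genes and chaperone and ERAD genes. In HT all 13 measured ATF4 and amino acid genes were lower within both replicate numbers, with a median log2 change of -1.12, from -0.75 to -2.44 in CHAC1. The 9 chaperone and ERAD genes went both ways, from -0.79 to 0.58 with 5 lower, and 1 was called with short genes left out. Their median was 0, so the medians of the parts lay 1.12 apart. In SUDHL6 the medians were -0.53 over 14 genes and 0.09 over 9, 0.62 apart. The lower list median may therefore reflect the amino acid genes more than the chaperone genes, a hypothesis found and tested on the same libraries.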
